A study of Homo sapiens with 8 samples.

How the data were processed

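The series measured the start codon contexts, known as Kozak sequences, of a reporter in HEK293T cells, a human embryonic kidney cell line. Per the labels, variants of 11 bases were synthesised on a microarray, each with the start codon in the middle, 4 bases before it and 4 bases after it. They were cloned into a vector, and transduced cells were sorted into 4 gates by the ratio of the fluorescent proteins EGFP and mCherry. Per the labels, genomic DNA of each sorted population went through a first PCR of the variant region and a second PCR that added sequencing adapters, and the products were mixed in equal molar amounts. The series holds 8 samples, which are gates 1 to 4 of library A and gates 1 to 4 of library B. Per the series design, the libraries were transduced independently, and library B was made with a lower rate of synthesis errors. Each gate therefore has 2 replicates, 1 from each library.

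The deposited table gives raw read counts per 11-base sequence and sample, and no normalization had been applied to these counts by the authors as far as the values show. The submitters' processing notes name CASAVA 1.8 and the genome build GRCh38.p14, without their roles. The rule by which reads were matched to sequences, any tolerance for mismatches and any filter on reads are not given in the sources used here. The counts come from PCR products and no molecular identifiers are mentioned, so that reads are not independent molecules and precision from counts covers counting error only. Because the products were mixed in equal amounts, the number of cells per gate is not in the counts, and all values describe the composition of each gate relative to the other gates.

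The table lists 4838 different sequences, of which 4812 carry ATG as the start codon, 23 CTG, 2 GTG and 1 CTC. Total counts per sample ran from 733743 to 943595. The median sequence had 473 counts over the 4 gates of library A and 507 over those of library B. In library A 951 sequences and in library B 889 sequences had under 100 counts, and 33 and 31 sequences had none. Positions are counted from the A of the start codon as +1, and the base before it is -1. The table has no gene names, and a genome was not used here, so that the gene from which a sequence was derived, its genomic position and its annotation are not reported, and the part of the naming rule that concerns genes had nothing to apply to.

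Counts were analysed in R 4.3.3. Sequences were kept by the filterByExpr function of edgeR 4.0.16 with a minimum count of 10, which left 4723 sequences and removed 115. Library sizes were scaled by trimmed means of M values (TMM). The main test was the quasi-likelihood F test of edgeR on the slope of log2 frequency per gate number, with the library as a block. The block comes from the design, because the 4 gates of a library are parts of 1 transduced pool. As a check, the deviations of the samples from the gate means correlated at 0.900 to 0.947 across sequences between gates of the same library. Log2 CPM (counts scaled to equal sample totals) correlated at -0.000845 to 0.148 between samples of different libraries, at 0.778 to 0.935 between gates of library A and at 0.809 to 0.952 between gates of library B. Further contrasts in the same framework were any difference among gates, gate 4 against gate 1, each pair of neighbouring gates, and the interaction of library and gate number. All p-values of these tests were adjusted by the Benjamini-Hochberg method over the sequences tested, with a threshold of 0.05.

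The mean gate of a sequence was the sum of the gate numbers weighted by the share of its CPM in each gate. It was computed for the 3229 sequences with at least 100 counts in each library. Sets of sequences were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between members. The sets were each base at each of the 8 variable positions (32 sets) and 9 context classes. Pairs of sequences that differ by exactly 1 C-to-T or A-to-G change were compared by the log2 ratio of their counts in each sample, after adding 0.5 to each count. The slope of the ratio per gate was tested with limma, again with the library as a block. Native sequences of genes were to serve as the first members of these pairs, but they were not known here, so the member with C or A was used instead, as had been laid down for that case. A pair needed at least 100 counts of each member in each library, which 5132 of 10594 pairs had. Mean differences per position and kind of change were tested by a two-sided permutation test that flips the sign of each pair's difference, with 100000 resamples. An additive model of the 8 positions was fitted to the mean gate in 1 library on 10 folds and scored on the held-out sequences in the other library. Figures were drawn with matplotlib 3.10.9.

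The tests were tried on simulated counts with each sequence's mean per library and the library sizes of the real samples. All sequences were given the same dispersion and were drawn independently, and most had no slope. This setting is simpler than the real counts, so that the rates below may not hold for them. Among 4723 simulated sequences, the trend test called 98% of those with a true slope of 1 in the right direction and 43% of those with a true slope of 0.5, and 4.08% of its calls had no true slope. In 5059 simulated pairs, 83.8% of true differences of 1 or more were called, and 3.52% of the calls had no true difference. The interaction test gave 0 calls where none had been simulated.

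The alternatives tried were total-count scaling, the size factors of DESeq2, no filter, a filter of 100 counts per library, DESeq2 1.42.0 in place of edgeR, no block, and each sample and each library left out. For sets, pairs, mean gates and the additive model they were an estimated correlation, other count minimums, another pseudocount, weights, and other outcomes. The filters on second codons and start codons were added after the data had been seen. The rules for naming sequences were fixed before the data were examined. They take the 10 largest positive and 10 largest negative slopes past the threshold with the same sign in both libraries, the same numbers of pairs, the 5 genes with most changed pairs in each direction, and the 2 most counted members of the class that begins with CACCATGG or CGCCATGG. Sequences named outside these rules are marked as chosen after their values were seen.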

Results

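The series followed 4838 start codon contexts of 11 bases through a sort of HEK293T cells, a human embryonic kidney line, into 4 gates of the EGFP to mCherry ratio. EGFP and mCherry are green and red fluorescent proteins, and the series used their ratio as a measure of how strongly each Kozak sequence drives translation. Each gate was sequenced in 2 independently transduced libraries, A and B, which gives 8 samples and n = 2 replicates per gate. In library A the total counts of gates 1 to 4 were 733743, 860436, 779921 and 782128. In library B they were 764975, 943595, 762384 and 770337. The composition of a gate was spread over many sequences, with an effective number of 2637 to 3142 sequences per sample. The labels do not say whether gate 1 or gate 4 held the highest ratio. A sequence that rose is one whose frequency increased with the gate number past the threshold, and a sequence that fell is one whose frequency decreased.

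The first comparison asked which sequences changed in frequency along the gates. Of 4723 sequences tested, 498 rose and 774 fell, together 1272 or 26.9%. The median slope was 0.43 log2 units per gate among the rising and -0.80 among the falling sequences, so that the falls were steeper. Of the 1272 sequences, 1255 had slopes of the same sign in both libraries fitted alone. A library fitted alone has 1 sample per gate, so that calls from it rest on scatter about a straight line and not on replicates. The test was the quasi-likelihood test of edgeR with the library as a block and Benjamini-Hochberg adjustment, and 1811 sequences had an unadjusted p under 0.05. With total counts in place of TMM factors the split was 642 rising to 689 falling, and without the library block no sequence passed in edgeR (597 at an unadjusted p under 0.05). The rising count depended on single samples, with 242 without gate 4 of library A and 204 without gate 4 of library B. Library A alone gave 765 sequences (175 rising) and library B alone 810 (181 rising), with 390 called in both and 389 of these in the same direction.

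The sequences with the largest rising slopes were described by the second residue and the bases around the start codon. Among the 10 named, 6 encode alanine as the second residue, 2 glutamate, 1 aspartate and 1 glutamine. In 9 of the 10 the base at +4 was G, in 7 the base at -3 was a purine, and in none was the base at +5 G or T. Of all 4723 sequences tested, 2056 carry G at +4, 2080 A at -3 and 1769 G at -3. Enrichment among the 10 was not tested. GGGGATGGCAA rose by 1.08 ± 0.26 log2 units per gate (SE, adjusted p = 0.00676, edgeR), with a mean gate of 3.23 ± 0.0806 (SD, n = 2). CGGGATGGCAG rose by 0.98 ± 0.15 (adjusted p = 0.000606) with a mean gate of 3.25 ± 0.196. ACCGATGGCAG rose by 1.00 ± 0.25 (adjusted p = 0.00861) and GGTCATGGCCT by 0.92 ± 0.22 (adjusted p = 0.00731), and GGTCATGGCCT had 101 counts in library A (slope 1.47) against 748 in library B (0.64). The other named sequences, ACCAATGGCGA, ACCCATGGAGC, GACGATGGCTG, TACTATGGATG, CGGTATGGAGC and GGCCATGCAGA, had slopes of 1.19, 1.08, 0.98, 0.95, 0.94 and 0.89. Each of these had under 100 counts in at least 1 library, and ACCAATGGCGA and ACCCATGGAGC had 4 counts each in library B. GGGGATGGCAA did not pass in library B alone (adjusted p = 0.0791), and ACCGATGGCAG did not pass in library A alone (slope 0.60, adjusted p = 0.237) or without gate 4 of library B (adjusted p = 0.0664). All 6 of the thinly counted sequences lost the threshold when samples were left out. Without gate 1 of library A the adjusted p was 0.0913 for ACCAATGGCGA, 0.299 for ACCCATGGAGC (slope 0.64), 0.0755 for GACGATGGCTG, 0.0585 for TACTATGGATG and 0.10 for CGGTATGGAGC. Without gate 4 of library A it was 0.106 for ACCAATGGCGA, 0.175 for GACGATGGCTG and 0.0918 for CGGTATGGAGC, and without gate 4 of library B it was 0.101 for ACCCATGGAGC, 0.127 for CGGTATGGAGC and 0.0571 for GGCCATGCAGA. ACCCATGGAGC also missed the threshold without gate 3 of library A (0.0855) and without gates 1, 2 or 3 of library B (0.0830, 0.0786 and 0.0691), and CGGTATGGAGC without gates 2 or 3 of library B (0.0566 and 0.0537). In library B alone the adjusted p was 0.414, 0.272, 0.699, 0.104 and 0.158 for ACCAATGGCGA, ACCCATGGAGC, GACGATGGCTG (slope 0.30), TACTATGGATG and CGGTATGGAGC, and in library A alone 0.136, 0.181 and 0.397 for ACCCATGGAGC, CGGTATGGAGC and GGCCATGCAGA.

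The sequences with the largest falling slopes encode glycine in 5 cases, valine in 3, alanine in 1 and serine in 1, and 2 of the 10 carry CTG in place of ATG. The base at +4 was again G in 9 of the 10, and the base at -3 was a purine in 6. Where both libraries gave a mean gate, it lay between 1.43 and 1.58. Sequences with a stop codon directly after the ATG averaged 1.81. The 10 were picked as extremes, so that their lower values are no measure of weaker expression than a stop codon leaves. CCGCATGGGAG had a slope of -1.46 ± 0.20 (SE, adjusted p = 0.000409, edgeR), a mean gate of 1.43 ± 0.144 (SD, n = 2) and 74.2% ± 11.3 of its CPM (counts scaled to equal sample totals) in gate 1. CAAGATGGGCT had a slope of -1.37 ± 0.17 (adjusted p = 0.000340) and a mean gate of 1.48 ± 0.241, with a slope of -2.23 in library A and -1.11 in library B. ATTCATGAGCC, the serine member, had a slope of -1.40 ± 0.23 (adjusted p = 0.000795) and a mean gate of 1.58 ± 0.150. AGGCCTGGCTC, which starts with CTG, had a slope of -1.37 ± 0.30 (adjusted p = 0.00393), with -2.59 in library A, -0.88 in library B and -0.86 without gate 1 of library A. The glycine sequences GCAGATGGGCA and GGCGATGGGAG had slopes of -1.45 and -1.38. GCAGATGGGCA had a slope of -3.76 in library A and -0.83 in library B. GGCGATGGGAG had 40 counts in library B and did not pass there alone (adjusted p = 0.0622). The remaining 4 were counted thinly in 1 library. GTCCATGGTCG (slope -2.35) had 7 counts in library B, GGGTATGGTCG (-1.74) had 9 in library A, CATCATGGGTA (-1.72) had 5 in library B, and GGGTCTGGTTT (-1.37) had 1 in library B. GTCCATGGTCG and CATCATGGGTA had no counts in gate 4 of either library, so that the size of their fitted slopes is uncertain and depends in part on the prior count. The same holds for the library A slopes of GCAGATGGGCA and AGGCCTGGCTC, which had no counts in gate 4 of library A. GGGTATGGTCG had all its library A counts in gate 1, so that its slope there rests on the prior count and is no measured size. In library B alone the adjusted p was 0.621 for GTCCATGGTCG (slope -0.54, against -3.84 in library A), 0.397 for CATCATGGGTA (-1.11) and 0.781 for GGGTCTGGTTT (-0.49), while GGGTATGGTCG passed with a slope of -1.59 there and -3.73 in library A. Without gate 1 of library A the adjusted p was 0.145 for GTCCATGGTCG (slope -1.45) and 0.214 for GGGTCTGGTTT, and without gate 4 of library A it was 0.0655 for CATCATGGGTA and 0.0799 for GGGTCTGGTTT.

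The next comparisons asked where along the gates the composition changed. Gate 1 stood apart by the number of calls between neighbouring gates, while the median absolute changes differed less. Between gates 4 and 1, 416 sequences were higher and 683 lower in gate 4 (edgeR, Benjamini-Hochberg). Between gates 2 and 1, 7 were higher and 369 lower in gate 2, with a median absolute change of 0.48 log2 units over all sequences. No sequence passed between gates 3 and 2 or between gates 4 and 3 in edgeR, where the median absolute changes were 0.37 and 0.35 and 254 and 202 sequences had an unadjusted p under 0.05. DESeq2 called 2 sequences between gates 3 and 2, CAGAATGGTGG (-0.89) and CAGGATGGTGG (-1.04), and 1 between gates 4 and 3, TAGGATGGCCG (1.00). These 3 are named after their values were seen. Allowing any pattern among the gates, 727 sequences differed. Without the library block no sequence passed in these edgeR tests, with 193 at an unadjusted p under 0.05 for any pattern, 343 between gates 4 and 1 and 139 between gates 2 and 1.

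The split between higher and lower calls depended on the scaling of the samples. Total-count scaling moved the median log2 change of all sequences up by 0.20 between gates 4 and 1 and by 0.31 between gates 2 and 1. The splits became 698 higher to 636 lower for gate 4 against gate 1, and 76 higher to 284 lower for gate 2 against gate 1. Relative to TMM the size factors of DESeq2 moved these medians by 0.013 and 0.043. The count for gate 4 against gate 1 was 602 (140 higher) without gate 4 of library A and 697 (157 higher) without gate 4 of library B, and 272 were higher without gate 2 of library A. The count for gate 2 against gate 1 was 89 without gate 2 of library A and 195 without gate 2 of library B. The 7 higher in gate 2 became 23 without gate 1 of library A, 145 without gate 1 of library B, 0 without gate 2 of library A, and 3 each without gate 2 of library B and gate 3 of library A.

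Library B was made with fewer synthesis errors, and the interaction of library and gate number asked whether sequences sorted differently in the 2 libraries. No sequence passed in edgeR, with 363 at an unadjusted p under 0.05, and DESeq2 called 12 sequences. Without gate 2 of library A, edgeR called 3, CATTATGGAGG, CTAAATGACTG and CGGAATGTAAC, named after their values were seen. No base set or context class differed in slope between the libraries either, the smallest adjusted p being 0.995 over the base sets, 0.967 over the 9 context classes and 0.653 for the start codons other than ATG (limma camera).

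Sequences kept similar places along the gates in the 2 libraries. The mean gate of 3229 sequences correlated between the libraries with a Pearson r of 0.767 and a Spearman rho of 0.684, across sequences, which are not independent replicates. The median mean gate was 2.58 in library A and 2.59 in library B, and the median absolute difference between the libraries for a sequence was 0.142 gate. The correlation rose with depth. It was 0.863 (rho 0.767) for the 1308 sequences with at least 500 counts in each library and 0.700 (rho 0.639) for the 3921 with at least 20.

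**Figure D1:**
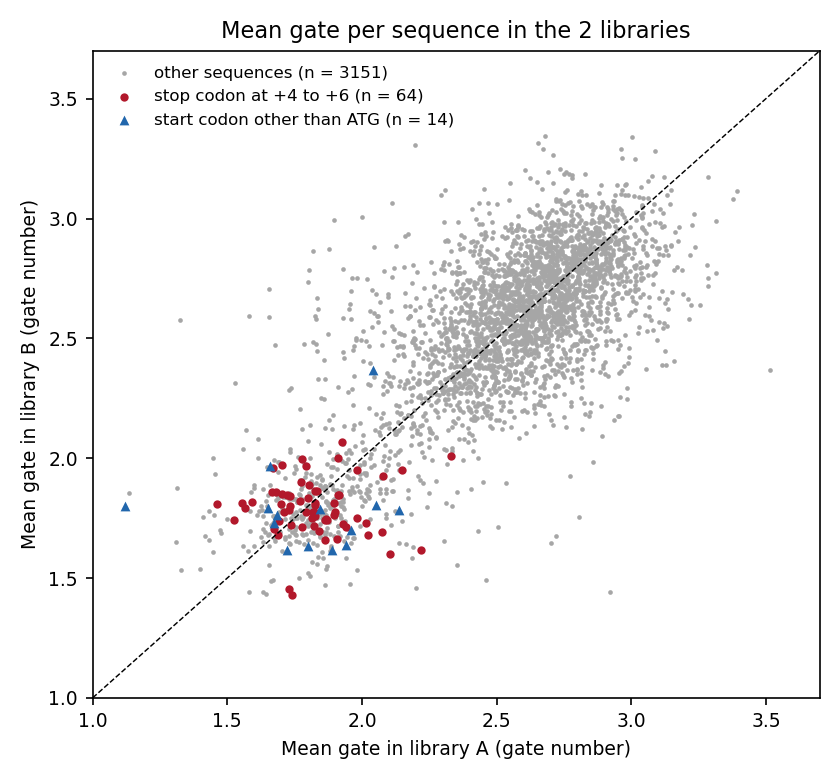
Mean gate (gate number) of each of 3229 sequences in library A (x axis) and library B (y axis), with the dashed line marking equal values. Red circles are the 64 sequences with a stop codon directly after the ATG, blue triangles the 14 with another start codon, and grey points the other 3151. The stop codon sequences lie around 1.81 in both libraries, against a median of 2.58 and 2.59 for all.

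The base sets asked which base at which position went with higher or lower gates. Of 32 sets, 4 lay higher and 7 lower than the other sequences (limma camera, preset correlation). The largest differences were those of T at -3 and of C and G at +5. At +5, C lay higher by 0.36 log2 units per gate (adjusted p = 1.07e-16), G had a difference of -0.37 (adjusted p = 1.82e-11) and T of -0.19 (adjusted p = 3.42e-06). With an estimated correlation the adjusted p was 0.0353 for C, 0.109 for G and 0.0651 for T at +5, so that C passed and the others did not. Of 1399 sequences with C at +5, 355 rose and 68 fell (376 and 72 adjusted over the list alone). Of 803 with G at +5, 37 rose and 307 fell (49 and 325 adjusted over the list alone), and of 1139 with T, 16 rose and 223 fell (13 and 206 adjusted over the list alone). At -3, the position at which a purine is the best known feature of strong Kozak sequences, A lay higher by 0.17 (adjusted p = 0.000478), C had a difference of -0.25 (adjusted p = 5.14e-07) and T of -0.41 (adjusted p = 2.86e-17). With an estimated correlation the adjusted p was 0.107 for A and 0.0651 for C and for T at -3. Of 2080 sequences with A at -3, 276 rose and 203 fell (238 and 194 adjusted over the list alone). Of 428 with C, 10 rose and 121 fell (11 and 126 adjusted over the list alone). G at -3 had a difference of 0.057 that did not pass (adjusted p = 0.404), with 208 of 1769 rising and 256 falling (204 and 253 adjusted over the list alone).

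Smaller differences were found at +4, -4 and +7. A at +4 lay higher by 0.18 (adjusted p = 0.000478, limma camera; adjusted p = 0.125 with an estimated correlation), with 171 of 1305 rising and 111 falling (140 and 102 adjusted over the list alone). T at +4 had a difference of -0.11 (adjusted p = 0.0172; adjusted p = 0.136 with an estimated correlation), with 47 of 659 rising and 143 falling (54 and 146 adjusted over the list alone). G at +4, the other base of the Kozak consensus, had a difference of -0.085 that did not pass (adjusted p = 0.474), with 254 of 2056 rising and 452 falling (282 and 469 adjusted over the list alone). At -4, A lay higher by 0.12 (adjusted p = 0.0270; adjusted p = 0.284 with an estimated correlation), with 161 of 1183 rising and 117 falling (135 and 106 adjusted over the list alone). T at -4 had a difference of -0.12 (adjusted p = 0.0172; adjusted p = 0.109 with an estimated correlation), with 55 of 844 rising and 184 falling (57 and 186 adjusted over the list alone). C at +7 had a difference of -0.10 (adjusted p = 0.000920; adjusted p = 0.284 with an estimated correlation), with 11 of 1132 rising and 149 falling (5 and 101 adjusted over the list alone). No base at -2, -1 or +6 passed. For C at -4 and G at +7 the mean difference was negative (-0.0024 and -0.032) while the median difference (0.018 and 0.11) and the direction of the test were positive.

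Library A alone lowered the number of lower sets from 7 to 4 (T at -4, T at +4 and C at +7, the last at -0.066, no longer passed), and A at -4 passed neither in a library alone, nor without the block (adjusted p = 0.0504), nor with at least 100 counts in each library (adjusted p = 0.0809). Leaving out sequences with a stop codon at +4 to +6 or another start codon, a filter chosen after the data were seen, turned the difference for T at +4 to 0.0061 (adjusted p = 0.575) and ended the call for A at -4 (adjusted p = 0.0548). Leaving out glycine and valine codons as well turned G at +4 to 0.18 (adjusted p = 1.23e-06) and brought A at +4 to 0.012 (adjusted p = 0.790). Under it C at +4 (-0.17, adjusted p = 3.57e-06) and G at -3 (0.12, adjusted p = 0.00580) passed, T at +4 passed again (-0.12, adjusted p = 0.00259), and G at +7 turned to 0.12 (adjusted p = 0.000744). C at +7 became -0.18 (adjusted p = 4.13e-08), A at -4 became 0.065 (adjusted p = 0.281), and the differences at +5 became -0.11 for G (adjusted p = 0.0101) and 0.23 for C (adjusted p = 4.15e-11). Glycine and valine codons all begin with G at +4, so that this filter takes sequences that lie low from the contexts with G at +4 alone, and the changes at +4 follow in part from its construction.

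**Figure D2:**
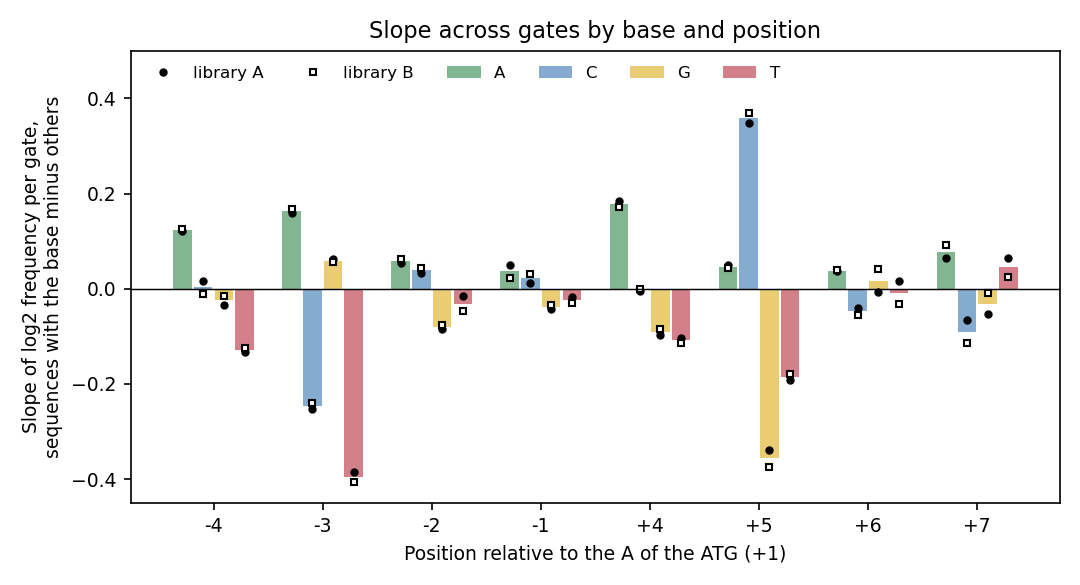
Difference in slope (log2 frequency per gate) between sequences with a base at a position and all other sequences, for the 8 variable positions. Bars are the mean of the 2 libraries fitted alone, filled circles library A and open squares library B. The largest bars are C and G at +5 and T at -3, and in each of these the libraries lie on the same side of 0.

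The context classes asked whether textbook grades of Kozak sequences went with the gates. Weak contexts, with neither a purine at -3 nor G at +4, lay lower by -0.41 log2 units per gate (limma camera, adjusted p = 3.13e-21; 0.0352 with an estimated correlation). Of 450 tested, 190 fell and 1 rose, GCAGATGTCGG (214 and 3 adjusted over the list alone), and their mean gate was 2.18 ± 0.00596 (SD, n = 2). Adequate contexts, with 1 of the 2 features, lay higher by 0.15 (adjusted p = 0.00549; adjusted p = 0.146 with an estimated correlation), with 256 of 2641 rising and 257 falling (174 and 225 adjusted over the list alone). Strong contexts, with both features, were not different from the others (mean difference -0.0058, median difference 0.063, adjusted p = 0.601). Of 1632 strong contexts, 241 rose and 327 fell (269 and 337 adjusted over the list alone). Leaving out glycine and valine codons with the stop codons and other start codons ended the call of the adequate class (0.034, adjusted p = 0.872) and turned the strong class to 0.27 (adjusted p = 8.25e-16). That filter, chosen after the data were seen, takes glycine and valine codons from contexts with G at +4 alone, so that the change of the strong class follows in part from its construction. T at -3 alone, also fixed as a class, had a difference of -0.41 (adjusted p = 2.68e-18; 0.0352 with an estimated correlation) with 194 of 446 falling (215 adjusted over the list alone). The 4 that rose, ATAAATGGCCT, CTAAATGGCTG, GTAGATGGCCT and GTAGATGGCTT, were named after their values were seen (6 rose adjusted over the list alone), as was GCAGATGTCGG.

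Sequences with a stop codon at +4 to +6 had the lowest places among the 9 classes. Of 90 tested, 81 fell and 0 rose (85 and 0 adjusted over the list alone). Their difference in slope was -0.89 (adjusted p = 5.50e-33; adjusted p = 0.146 with an estimated correlation). Their mean gate was 1.81 ± 0.0224 (SD, n = 2), with 55.1% ± 1.01 of a sequence's CPM in gate 1 and 10.9% ± 0.657 in gate 4. Sequences with a start codon other than ATG, a class added after the data were seen, lay in the same range. Of 23 tested, 18 fell and 0 rose (22 and 0 adjusted over the list alone), with a difference of -0.89 (adjusted p = 9.70e-12; adjusted p = 0.0708 with an estimated correlation) and a mean gate of 1.79 ± 0.00910.

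**Figure D3:**
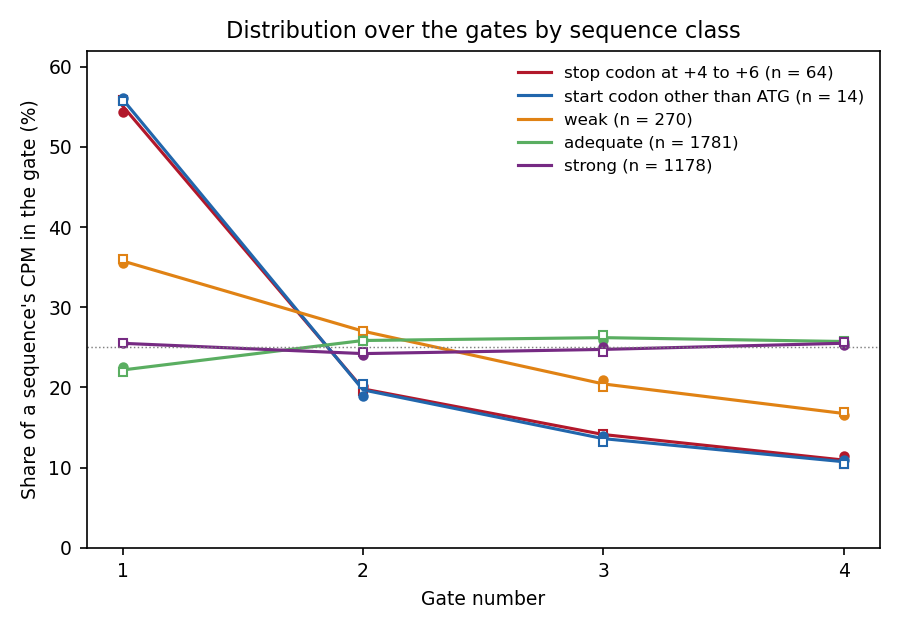
Share of a sequence's CPM (y axis, percent) in each gate (x axis, gate number), averaged over the sequences of a class. Lines are the mean of the 2 libraries, filled circles library A, open squares library B, and the dotted line marks equal shares. Stop codon sequences and other start codons hold 55.1% and 55.9% in gate 1, weak contexts 35.8%, strong contexts 25.5% and adequate contexts 22.2%.

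Additional ATG codons and the bases directly before the start were the remaining classes. An ATG that begins at -4, out of frame with the main start, lay lower (-0.28, adjusted p = 0.000995; adjusted p = 0.146 with an estimated correlation, limma camera). Of 15 such sequences 4 fell (4 adjusted over the list alone), ATGAATGAACC, ATGAATGAATT, ATGAATGACCT and ATGCATGAAAT, and 0 rose. All 15 carry T at -3, a base whose set had a difference of -0.41, so that this class does not separate the ATG from that base. An ATG that begins at -3, in frame, made no difference that passed (-0.0091, adjusted p = 0.672). All sequences of this class carry A at -3, a base whose set lay higher by 0.17, so that the ATG is not separated from that base here either. Of 40 sequences GATGATGTCCA and TATGATGAAGA rose and CATGATGGGTT and GATGATGCTGA fell (0 and 1 adjusted over the list alone). An ATG that begins at +5 lay higher by 0.20 (adjusted p = 0.00549; adjusted p = 0.146 with an estimated correlation), by 0.20 (adjusted p = 0.0681) without the library block, and by 0.072 (adjusted p = 0.289) without stop codons, other start codons and glycine and valine codons. Of 80, AACAATGAATG, AGCAATGGATG, CAAGATGAATG, GAAGATGAATG and TACTATGGATG rose, and TTCAATGTATG and TTCGATGTATG fell (0 in either direction adjusted over the list alone). These members, apart from TACTATGGATG, were named after their values were seen. CACC or CGCC before the start lay higher by 0.11, which did not pass (adjusted p = 0.0676), with 20 of 134 rising and 16 falling, and the same counts adjusted over the list alone. Without stop codons, other start codons and glycine and valine codons it passed (0.11, adjusted p = 0.0350).

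The consensus CACCATGG or CGCCATGG was spread over much of the range. Of 67 such sequences 12 rose and 13 fell (13 and 14 adjusted over the list alone), with mean gates from 1.59 to 3.01. The most counted members both encode alanine and rose. CACCATGGCCG, with 3125 and 6389 counts in libraries A and B, had a slope of 0.41 ± 0.077 (SE, adjusted p = 0.00168, edgeR) and a mean gate of 2.90 ± 0.0974 (SD, n = 2). CACCATGGCCA had a slope of 0.37 ± 0.074 (adjusted p = 0.00231) and a mean gate of 2.87 ± 0.0302. Neither passed in library B alone (adjusted p = 0.101 for CACCATGGCCG and 0.0951 for CACCATGGCCA).

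Pairs of sequences that differ by 1 C-to-T or A-to-G change, which are among the changes base editors make, asked which single changes move a context along the gates. Of 5132 pairs, 263 fell and 35 rose, in each case with the same sign in both libraries (limma, Benjamini-Hochberg; 922 pairs at an unadjusted p under 0.05). This split holds for pairs read from the member with C or A. Read as T-to-C or G-to-A changes, the same pairs would give 263 rises and 35 falls. Of the 298, 277 had the change after the start codon, 149 of them at +5 and 89 at +4, and 21 had it before. Of the 22 pairs that gain a stop codon 16 fell, with mean differences of -0.87 in library A and -0.98 in library B. Of the 21 pairs that lose one, 2 rose, CGAGATGTGAC to CGAGATGTGGC and TGAAATGTAGA to TGAAATGTGGA, named after their values were seen. The mean differences over these 21 pairs were 0.53 in library A and 0.58 in library B. All 22 gains start from glutamine, whose sequences had a mean gate of 2.66. All 21 losses lead to tryptophan, whose sequences had a mean gate of 2.35, so that gains and losses are not alike. Pairs share members and are therefore not independent.

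Among the 10 pairs with the largest falls, 7 change alanine to valine as the second residue and 3 change another residue to glycine. Substitutions are written with the base of the first sequence, the position counted from 1 at the start of the 11 bases, and the base of the second sequence. TACTATGGCCG to TACTATGGTCG (C9T, alanine to valine) had a slope difference of -1.70 ± 0.18 log2 units per gate (SE, adjusted p = 0.00306, limma), and the mean gates were 3.05 ± 0.136 and 1.69 ± 0.0101 (SD, n = 2). TATCATGGCTG to TATCATGGTTG (C9T) had a difference of -1.64 ± 0.18 and CGGGATGGCGG to CGGGATGGTGG (C9T) of -1.48 ± 0.18. AATCATGAGAA to AATCATGGGAA (A8G, arginine to glycine) had a difference of -1.78 ± 0.34 (adjusted p = 0.0125), with -2.49 in library A and -1.08 in library B, and did not pass without gate 1 of library A. It was -1.16 without gate 4 of library A and -1.19 with weights from the counts. The remaining 6 lay between -1.61 and -1.45. At the first end, AATCATGGAAA to AATCATGGGAA (A9G) had -2.38 in library A, -0.83 in library B, -1.06 with weights from the counts and -1.03 without gate 4 of library A. It did not pass without that sample (adjusted p = 0.0639), without gate 1 of library A (adjusted p = 0.112) or with at least 20 counts of each member (adjusted p = 0.0558), and CATCATGGATG to CATCATGGGTG (A9G) did not pass without gate 1 of library B (adjusted p = 0.0595). Among the 10 largest rises, 3 change proline to serine, as in CAGCATGCCGG to CAGCATGTCGG (C8T), with a difference of 1.09 ± 0.17 (adjusted p = 0.00621). ATAAATGACCT to ATAAATGGCCT (A8G, threonine to alanine) had the largest at 1.21 ± 0.19 (adjusted p = 0.00680), with mean gates of 2.16 ± 0.263 and 3.13 ± 0.0207. Another 4 keep the second residue as read from the main start, such as CACGATGGGCT to CATGATGGGCT (C3T), which had a difference of 0.96 ± 0.14 (adjusted p = 0.00535). The change in that pair also makes an ATG that begins at -3, in frame, so that the pair does not separate a change of context from an added start codon.

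Of the 10 named rises, 6 lost the threshold when single samples were left out. They were TGTCATGGAGA to TGTTATGGAGA (C4T), GGAGATGGCAA to GGGGATGGCAA (A3G), GTGGATGAATT to GTGGATGGATT (A8G), CTTCATGGACT to CTTCATGGATT (C10T), GCAGATGCCGG to GCAGATGTCGG (C8T) and GCGGATGAAGA to GCGGATGGAGA (A8G), of which the first, the second and the CTTCATGGACT pair keep the second residue. In that order the adjusted p was 0.146, 0.127, 0.0664, 0.0805, 0.112 and 0.0658 without gate 1 of library A, and 0.159, 0.127, 0.0814, 0.0908, 0.105 and 0.0796 without gate 1 of library B. Without gate 4 of library B it was 0.0592, 0.0573, 0.0731 and 0.109 for the pairs of TGTCATGGAGA, GGAGATGGCAA, GTGGATGAATT and GCAGATGCCGG. The pairs of TGTCATGGAGA and GGAGATGGCAA also missed the threshold without gate 3 of library A (0.0661 and 0.0528), gate 4 of library A (0.0987 and 0.0594) and gate 3 of library B (0.0741 and 0.0589). With at least 20 counts of each member the adjusted p was 0.0792, 0.0660 and 0.0578 for the pairs of TGTCATGGAGA, GGAGATGGCAA and GCAGATGCCGG, and with weights from the counts the GGAGATGGCAA pair had a difference of 0.53 (adjusted p = 0.479).

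The number of called pairs moved with the samples and the settings. It was 125 without gate 1 of library A, 73 without gate 1 of library B, 192 without gate 3 of library B and 175 without gate 4 of library B. The 35 rises became 7 without gate 1 of either library, 20 without gate 3 or gate 4 of library A, 19 without gate 3 of library B and 16 without gate 4 of library B. Limma called no pair in library A alone (837 at an unadjusted p under 0.05), in library B alone (785) or without the library block (298). With at least 500 counts per member it called 95 pairs, and with weights from the counts 450.

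Averaged over all pairs of a kind, the changes at +5 were the largest. A C-to-T change at +5 (C9T, 298 pairs) moved the slope by -0.45 ± 0.00016 (SD, n = 2 libraries), with 85 falling and 1 rising, GGTGATGCCGG to GGTGATGCTGG. An A-to-G change at +5 (A9G, 260 pairs) moved it by -0.36 ± 0.062, with 62 falling and 1 rising, TGAAATGTAGA to TGAAATGTGGA. The sign-flip permutation test over pairs gave the smallest p its resamples allow, 1e-05, in both (adjusted p = 3.2e-05). It gave the same p for the A-to-G change at +4 (A8G, -0.11 ± 0.011, 58 of 476 falling and 7 rising). Of those 58 falls, 26 change arginine to glycine, 16 serine to glycine, 15 methionine to valine and 1 asparagine to aspartate. The test treats pairs as independent although they share members, so that its p-values describe spread over pairs and not between libraries. At -3 the C-to-T change (C2T, 56 pairs) moved the slope by -0.13 ± 0.017 (adjusted p = 0.00167), or by -0.20 (adjusted p = 0.000267) with at least 20 counts of each member, while the A-to-G change (A2G, 551 pairs), which keeps a purine there, had a mean of -0.015 ± 0.018 that did not pass (adjusted p = 0.132). The C-to-T change at +7 (C11T, 254 pairs) had a positive mean of 0.11 ± 0.0086 (adjusted p = 3.2e-05), yet its called pairs, 5 in number, all fell. They were CAAGATGGGCC to CAAGATGGGCT, CACGATGGGCC to CACGATGGGCT, CGGCATGGGCC to CGGCATGGGCT, TAAGATGGGCC to TAAGATGGGCT and TACGATGGGCC to TACGATGGGCT, and in each the second residue is glycine. The pairs in this paragraph were named after their values were seen. Of the 16 combinations of position and kind 13 passed, against 8 in library A alone.

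**Figure D4:**
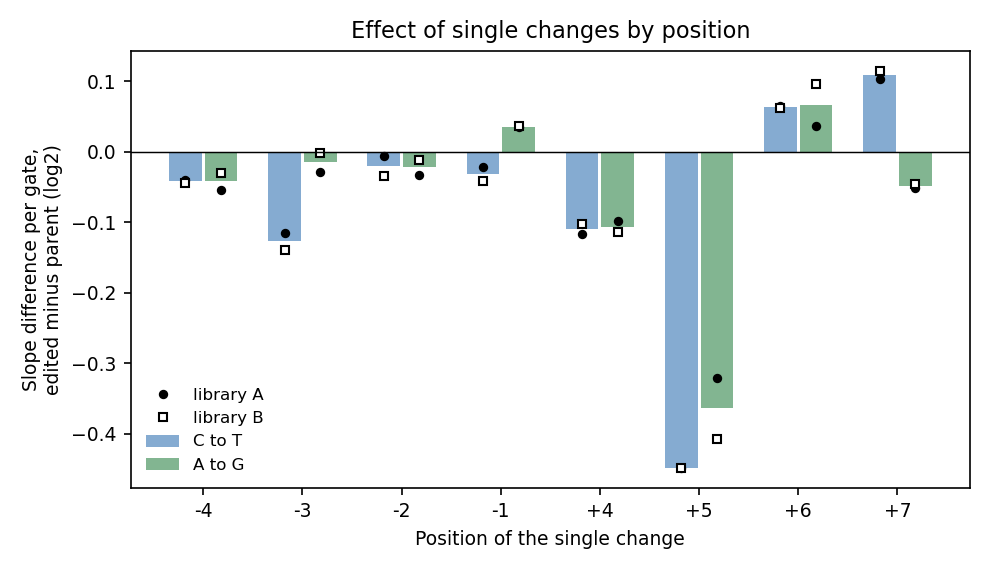
Mean difference in slope (log2 per gate) between the second and the first sequence of a pair, by position and kind of change. Bars are the mean of the 2 libraries, filled circles library A and open squares library B. Changes at +5 are the largest, -0.45 for C to T and -0.36 for A to G.

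The last comparison asked how far the 8 bases, taken as separate contributions, give the place of a sequence. The additive model fitted in 1 library and scored on held-out sequences in the other reached a Pearson r of 0.576 and an R squared of 0.330 over 3229 sequences, below the correlation of 0.767 between the libraries themselves. With terms for pairs of neighbouring positions it reached 0.737 and 0.539. These are values across sequences and have no replicate test.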

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

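Of 1340 values computed under alternatives, 1044 kept their direction and their side of the threshold or stayed within the limits set for counts, 190 kept their direction and lost the threshold, 6 gained it, 82 counts or correlations moved further, and 18 changed sign. Among values of the named sequences 280 stayed and 61 lost the threshold, and among those of the named pairs 232 stayed and 91 lost it, with no change of sign in either. Of the named sequences 12 lost the threshold in library B alone and 4 in library A alone, and all 22 without the block. Each gate has n = 2 libraries, and without 1 sample a gate rests on 1 library, which is assumed to vary like the others. Tests in a library alone have 1 sample per gate and measure scatter about a straight line, not variation between replicates. The median sequence had 473 counts over the gates of library A and 507 over those of library B, so that slopes of thinly counted sequences are uncertain. The filters on stop codons, other start codons and glycine and valine codons were chosen after the data had been seen, and the cause of the changes below was not tested unless stated.

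Total-count scaling moved the rising counts to 698 for gate 4 against gate 1 and 76 for gate 2 against gate 1, with the median of all sequences up by 0.20 and 0.31 log2 units, and the size factors of DESeq2 gave 12 for the latter. DESeq2 itself gave 38 rising for gate 2 against gate 1, 2 for gate 3 against gate 2, 1 for gate 4 against gate 3 and 12 for the difference between the libraries. Without the replicate block, edgeR gave 0 sequences for the trend, any gate, gate 4 against gate 1 and gate 2 against gate 1 (597, 193, 343 and 139 at an unadjusted p under 0.05), limma gave 0 pairs (298), and 1 context class lay higher in place of 2. The pairing of gates comes from the shared pool of a library, and the log2 totals of a sequence correlated between libraries at 0.165. With an estimated correlation 1 base set lay higher and 0 lower, and 0 classes higher and 2 lower. The correlation of mean gates was 0.700 (rho 0.639) with at least 20 counts and 0.863 (rho 0.767) with at least 500.

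Called pairs numbered 95 (10 rising, 85 falling) at 500 counts per member, where fewer pairs were tested, and 450 (95 rising) with weights, and 23 rose at 20 counts. The additive model gave 0.616 (R squared 0.373) at 500 counts and 0.737 (0.539) with terms for neighbouring positions.

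With single samples or a whole library left out, the counts ranged from 765 to 1198 for the trend (175 to 448 rising, 543 to 750 falling) and from 0 to 314 for the pairs (0 to 43 rising, 0 to 271 falling). With single samples alone left out, they ranged from 564 to 928 for any gate, from 602 to 1265 for gate 4 against gate 1 (140 to 600 rising, 462 to 694 falling), from 89 to 495 for gate 2 against gate 1 (0 to 145 rising, 89 to 415 falling) and from 0 to 3 for the difference between the libraries, with 0 each for the other neighbouring gates in edgeR. With a whole library left out, the only such setting run for them, base sets gave 3 higher and 4 to 7 lower, classes 2 higher and 4 lower, and single changes by position 8 to 10 past the threshold. The lowest trend counts came without library B (765) and without library A (810), and the lowest rising count among single samples without gate 4 of library B (204). Pairs numbered 0 with either library left out.

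Most changes of sign concerned differences near 0, and of the 18 the value first reported had passed its threshold in 1 and the alternative in 3. ATG at -3 turned to 0.046 with at least 100 counts, 0.017 without the block, 0.0049 without library A and 0.0013 without library B. C at -4 turned to 0.0022 without the block, 0.017 without library B (-0.011 without library A), 0.0056 without stop codons and other start codons and 0.015 without glycine and valine codons as well. C at +4 turned to 0.0054 without the block, and G and T at +6 to -0.0074 and 0.016 without library B (0.041 and -0.033 without library A). T at +4, which had passed, turned to 0.0061 without stop codons and other start codons. Without glycine and valine codons as well, G at -4 turned to 0.0031, A at -1 to -0.0022 and A at +5 to -0.063, while G at +4 (0.18), G at +7 (0.12) and the strong class (0.27) turned positive and passed. For G at +4 and the strong class this follows in part from the filter, because glycine and valine codons all begin with G at +4.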

Other observations

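All tests in this part were chosen after some results had been seen, except that of the order of the gates. The tests on glycine, serine codons, stop codons, G at +4 and the orders of the gates were written after base means and the largest slopes were known but before codon values were computed, and those on the base G outside glycine, GC content, the bases GG and the base at +7 after the values were known. The second residue, which the codon at +4 to +6 encodes, went with the place of a sequence more closely than the base at -3. Among sequences with ATG as the start codon, those with glycine there had a mean gate of 1.90 ± 0.0232 (SD, n = 2 libraries), and of 322 tested 235 fell and 0 rose. Tyrosine lay at 2.23 ± 0.0229, with 30 of 86 falling and 0 rising, and valine at 2.26 ± 0.0156, with 166 of 502 falling and 1 rising, GGTCATGGTTA. Alanine lay highest at 2.82 ± 0.0276, with 235 of 618 rising and 2 falling, GGCTATGGCCG and TTGTATGGCCC, and threonine and serine lay at 2.68 ± 0.0260 and 2.68 ± 0.00322. AGGCCTGGCTC, an alanine sequence that fell, starts with CTG and is not counted here. The adjusted p with an estimated correlation was 0.0735 for glycine, 0.00823 for tyrosine, 0.00751 for valine and 0.00891 for alanine (limma camera). The second residue fitted in 1 library gave an R squared of 0.451 in the other, the second codon 0.454, the base at -3 0.10 and the 4 bases before the start, taken as 1 label, 0.055. These values include stop codons as a residue label and sequences with another start codon, and the labels differ in number. The 4 bases scored below the base at -3 that they contain, so that 0.055 does not measure all they give.

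Pairs were also grouped by what the change does to the second residue, again read from the member with C or A. Of 662 pairs with a synonymous second codon 7 rose and 0 fell, with a mean slope difference of 0.047 ± 0.018 (SD, n = 2 libraries). Of 1168 pairs that change the residue 21 rose and 221 fell, with a mean of -0.24 ± 0.013. Of 696 pairs with a change at +7, 0 rose and 28 fell, and of 2606 with a change before the start 7 rose and 14 fell. Changes from alanine to valine fell in 76 of 161 pairs and from glutamate to glycine in 40 of 63. The mean gate also differed by the base at +7, the first of the third codon, in residues picked after their values were seen, so that permutation tests run on these groups are not used as evidence. Valine with G at +7 lay at 1.82 ± 0.0321 against 2.43 ± 0.00877 with another base, glycine with C at +7 at 2.32 ± 0.0466 against 1.78 ± 0.0162, and proline with G at +7 at 2.11 ± 0.0516 against 2.45 ± 0.0229. In alanine the difference for G went the other way, 2.88 ± 0.0572 against 2.78 ± 0.0115.

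The labels do not say which gate held the highest ratio. A stop codon directly after the start ends translation, so that such sequences should gather at the low end. Their median mean gate differed from that of all sequences by -0.778 (-0.758 in library A, -0.798 in library B). This argues against gate 1 as the highest, and gate 4 may therefore be the highest. A trend of 1272 sequences was larger than any from another order of library B's gates, of which 1 of 24, the real one, gave as many. Other orders that left gate 1 in its place gave 228 to 806, and all that moved it gave 0. The comparison thus shows mainly that gate 1 matched between the libraries. It does not exclude chance for the called sequences, because the mean gates were already known to correlate between the libraries.

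Sequences with G at +5 lay low, and explanations were compared by the mean gate. All groups compared here carry ATG as the start codon. Stop codons TGA were argued against, because without stop codons these sequences stayed at -0.249 from all such sequences without stop codons. Those with C at +5 lay at 0.197, where GC content would have put them as low as those with G. This does not decide on GC content. The place of C at +5 was known beforehand, and its codons encode only alanine, threonine, serine and proline. Glycine against the other sequences with G at +5 gave -0.641, so that glycine as the second residue is a candidate explanation, and the bases GG at +4 and +5 cannot be told apart from it, because 0 sequences have these bases without encoding it. A part of the base G itself stays open, since with stop codons and glycine left out on both sides G at +5 differed from the other bases by -0.0282 (-0.0188 in library A, -0.0375 in library B), and the test on serine codons gave a ratio of 0.292, each between the bounds written for it. Whether the protein is made less or lasts less long was not tested.

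Sequences with G at +4 lay below those with A at +4. Among sequences with A or C at +5, which excludes glycine and valine, G lay above A by 0.0563 gate (0.0601 in library A, 0.0526 in library B). That comparison takes the low glycine and valine codons from the G side alone and keeps alanine, the highest residue. With C at +5 alanine lay at 2.82 and threonine at 2.68. With A at +5 aspartate and glutamate (G at +4) lay at 2.51 and 2.62, against 2.64 and 2.58 for asparagine and lysine. The comparison therefore does not settle by itself whether glycine and valine codons account for the lower place of G at +4. Among pairs with an A-to-G change at +4, arginine to glycine fell in 26 of 41 and serine to glycine in 16 of 24. Methionine to valine fell in 15 of 44 and isoleucine to valine in 0 of 29. Threonine to alanine rose in 3 and fell in 0 of 170 pairs, and lysine to glutamate in 3 and 0 of 119. Asparagine to aspartate rose in 1 and fell in 1 of 49. Called falls thus came mostly with a change to glycine or valine. No other explanation of this pattern was tested.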
